A study of Homo sapiens with 10 samples.

How the data were processed

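Gene expression was measured on Affymetrix HG-U95Av2 oligonucleotide arrays in LNCaP C4-2 cells, an androgen-independent derivative of the LNCaP human prostate adenocarcinoma line. Per the labels, cells received 10 Sv of gamma radiation from a cesium source and were collected at 1, 2 and 4 h, then at 6, 8 and 12 h, and last at 16, 20 and 24 h. An unirradiated control was collected together with the 24 h cells. Each condition had 1 array, so no condition had replicates, and the number of arrays limits the precision of every value.

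Per the labels, the authors extracted total RNA with Trizol, made probe set signals with Microarray Suite 5 and processed them further in GeneSpring. The deposited values are linear signal intensity divided by the array's own median by the authors: every deposited column has a median of 1. The medians that were divided out were recovered from the spacing of the values and lay between 105.2 and 125.9 signal units. Multiplied back, the trimmed mean signal was 300.1 on every array, so the signals had been scaled to a common trimmed mean before the division by the median.

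The table held 12625 probe sets for 10 samples, of which 67 were control probe sets. The columns deposited as unirradiated and as 1 h were identical in all 12625 values, while no other pair of columns shared more than 1 value. The deposit therefore held 9 distinct arrays. The array given under both labels is called the shared array here, because the values cannot tell which of the 2 samples it is. No comparison of 1 h with the control was possible.

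Probe sets assigned to exactly 1 gene (10943) were kept, and each of the 8226 genes was represented by its probe set with the highest mean. BTG2 was not analysed here. An offset of 0.292, the median over arrays of the 25th percentile of signal, was added before taking log2. Arrays were quantile normalized, because their trimmed means as deposited differed by more than the limit of 1% set for using values unchanged. Genes with a mean above the 40th percentile were tested (4935 genes). Below, log2 differences and slopes are on this scale.

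The models were fitted with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance prior and Benjamini-Hochberg adjusted p under 0.05 as the threshold. The time trend was a slope over log2 hours across the 9 irradiated labels, the shared array standing for 1 h (7 residual degrees of freedom). The curved time course was a joint F test on log2 hours and its square (6 residual degrees of freedom), which a straight slope can also pass; the squared term was not tested alone. Genes past it are called curved. A curved gene is called arched when its squared term was negative and dipped when it was positive. Windows of early (2 and 4 h), middle (6, 8 and 12 h) and late (16, 20 and 24 h) arrays were each compared with the shared array as control (5 residual degrees of freedom). The lone control was assumed to vary like the window arrays, and the spread within a window includes changes over its hours. This departs from the plan, which put the 1 h column in the early window; because it is the control column again, the array was counted 1 time, and the planned version was run as an alternative. The late window was also compared with an early window of 1, 2 and 4 h, the shared array standing for 1 h (6 residual degrees of freedom). Single times were compared with the shared array as log2 differences without a test.

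Before the data were examined, 20 gene lists and 5 lists of cell type markers were fixed, along with the models, alternatives and the rule for naming genes. The lists were p53 target, G2/M and mitosis, G1/S and DNA replication, replication-dependent histone, DNA damage signalling and repair, apoptosis, immediate early, NF-kB, interferon-stimulated, androgen-responsive, cholesterol and lipid synthesis, unfolded protein response and amino acid stress, heat shock, NRF2 and oxidative stress, cytosolic ribosomal protein, respiratory chain, proteasome, glycolysis and hypoxia, neuroendocrine, and senescence and lysosome genes. They were tested against all other genes with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 20 lists. An estimated correlation and the rotation test fry were alternatives. At single times a list's median was ranked among 10000 random lists matched on expression. Enrichment of lists among curved genes was tested with Fisher's exact test against all tested genes, a test chosen after the data had been seen. It treats genes as independent and makes no allowance for correlation within a list.

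Genes were named by rule: for the trend the 12 largest slopes in each direction, for the curved time course the 6 smallest adjusted p among genes outside the trend, for each window contrast the 8 highest and 8 lowest differences, at the first time after the shared array (2 h, because 1 h could not be used) the 5 highest and 5 lowest, and up to 4 members of each list. A fixed set of damage, cell cycle and androgen genes was always reported, except BTG2 and 1 gene that is not reported here. Where none passed, the 4 smallest p were given. Other genes are named as examples and were chosen after their values had been seen.

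The alternatives were values as deposited, scaling to a common 75th percentile, a floor in place of the offset, a doubled offset, no filter, a filter at the 60th percentile, no intensity trend, all probe sets, hours in place of log2 hours, the control at 0 h, a fitted 24 h value, the 2 other list tests and leaving out each array in turn. After the data had been seen, 3 more were added: signals restored to equal trimmed means, the shared array under both labels, and the fit without 16 and 20 h. The late versus early fit without the shared array, reported among the arrays left out in turn, was also added then, as was keeping the main probe set of a named gene where a setting changed it. The models were tested on simulated data with 200 changed genes among 4935. A slope of 0.5 was recovered in 99.4% of the genes and a late versus early difference of 1 in 85.8%, with 4.95% and 5.79% false calls. A late difference from the control of 1 was recovered in 57.4% with 5.3% false calls. The simulated noise was normal and independent between genes and arrays, so these rates need not hold for the real arrays. Tables were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9.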

Results

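The data describe how transcript levels in LNCaP C4-2 prostate cancer cells changed over a day after a single gamma dose of 10 Sv. The 9 irradiated labels (1, 2 and 4 h, then 6, 8 and 12 h, and last 16, 20 and 24 h) and the unirradiated control had 1 array each, and the control and 1 h labels carried the same array, so 9 distinct arrays were compared. There were no replicates at any time. Errors of slopes and window differences come from the scatter of arrays around the fitted model. On all arrays the median value was 1, and values reached between 211.1 and 285.8.

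Signs of RNA quality set the 16 h array apart. The ratio of 3 prime to 5 prime signal was 3.30 for ACTB and 2.38 for GAPDH at 16 h, against 1.36 to 1.76 and 1.11 to 1.37 on the other arrays. The 20 h array had the next highest ratios, 1.76 and 1.37. Both arrays belong to the late window. Markers of luminal prostate epithelium were high, with a median value of 13.9 over 11 genes and 34.8 for KRT18. Basal, fibroblast, leukocyte and endothelial markers had medians of 0.677, 0.646, 0.552 and 0.541, below the array median of 1. Their highest genes lay above it: ITGA6 (4.13), COL6A1 (14.8), CD68 (2.71) and FLT1 (1.86).

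The time trend asked which genes had a rising or falling slope over log2 hours, the shared array standing for 1 h. A slope does not require a steady move in 1 direction. DDIT3, which encodes the stress-induced transcription factor CHOP, fell by 0.62 log2 units per doubling of time (SE 0.05, adjusted p = 0.00011), a fitted ratio of 24 h to 1 h of 0.138. The glycyl-tRNA synthetase gene GARS1 fell by 0.61 (SE 0.09), the asparagine synthetase gene ASNS by 0.59 (SE 0.12), the mitochondrial folate enzyme gene MTHFD2 by 0.58 (SE 0.07) and the amino acid transporter gene SLC7A5 by 0.52 (SE 0.07). In all, 94 genes fell and 42 rose among 4935 tested, 9 arrays each.

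Other genes with the largest falls were PCK2, the mitochondrial phosphoenolpyruvate carboxykinase (-0.49), CEBPB, a stress-responsive transcription factor (-0.48, adjusted p = 0.00011), PLK1, the mitotic kinase (-0.46), STC2, a secreted glycoprotein (-0.42), CTH, which makes cysteine (-0.42), HMGB2, a chromatin protein (-0.42) and CLGN, an endoplasmic reticulum chaperone (-0.41). Without 1 array the call of PLK1 was lost at 1, 2, 4, 8, 12, 16 or 24 h (adjusted p from 0.0515 to 0.188), that of ASNS at 2, 16, 20 or 24 h (0.0540 to 0.0923), that of CLGN at 2 or 20 h (0.102 and 0.0682) and that of CTH at 2 h (0.0836).

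The largest rises included ACTA2, smooth muscle actin and a member of the p53 list, at 0.72 per doubling (SE 0.10, adjusted p = 0.00359, fitted ratio 9.93); it was also the only one of 8 tested fibroblast markers that passed. CEL, a lipase, rose by 0.51 (SE 0.05, adjusted p = 0.00041), TP53I3, a p53-induced oxidoreductase, by 0.50 (SE 0.12, adjusted p = 0.0487) and APOD, a lipocalin, by 0.48 (SE 0.08). PPFIA4 (0.41), APLP1 (0.31), LRPAP1 (0.29), PLXNB2 (0.28), ASTN2 (0.27), the histone gene H2BC21 (0.23) and the kinase gene CLK3 (0.23) also rose. TOP3A, a topoisomerase, rose by 0.55, but its other probe set, with nearly the same mean signal (0.6854 against 0.7177), had a slope of 0.09. That probe set stood for the gene without 4, 12, 16 or 20 h, and TOP3A was then not called (slopes of 0.09, 0.12, 0.08 and 0.10); with the first probe set kept it was called without each of these (0.5066 to 0.5711). Calls were lost without 1 array for TP53I3 (any time but 24 h; adjusted p from 0.0588 to 0.228), ASTN2 (any time but 4 h; 0.0610 to 0.188), CLK3 (2, 4, 8, 12, 16, 20 or 24 h; 0.0507 to 0.130), H2BC21 (2, 20 or 24 h; 0.0671 to 0.104), PLXNB2 (1 or 2 h; 0.0766 and 0.0680) and PPFIA4 (2 h; 0.0538).

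Of the 28 tested unfolded protein response and amino acid stress genes, 18 fell, 0 rose and 10 did not pass; adjusted over the list alone, 22 fell. The list's median slope was -0.29 (camera adjusted p = 5.10e-26), with an adjusted p = 0.0603 with an estimated correlation and 0.00183 with fry. Besides the genes above, VEGFA fell by 0.30 (adjusted p = 0.000422), the transcription factor gene XBP1 by 0.24 (0.000894), ATF4, the main effector of this response, by 0.32 (0.00725), and the serine synthesis gene PHGDH by 0.32 (0.0245). The chaperone gene HSPA5 did not pass (slope -0.20, adjusted p = 0.118), except without the 1 h array (0.0231) and with the slope over hours (0.0122). The call of PHGDH was lost without 2, 20 or 24 h (adjusted p from 0.0689 to 0.0806).

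**Figure D1:**
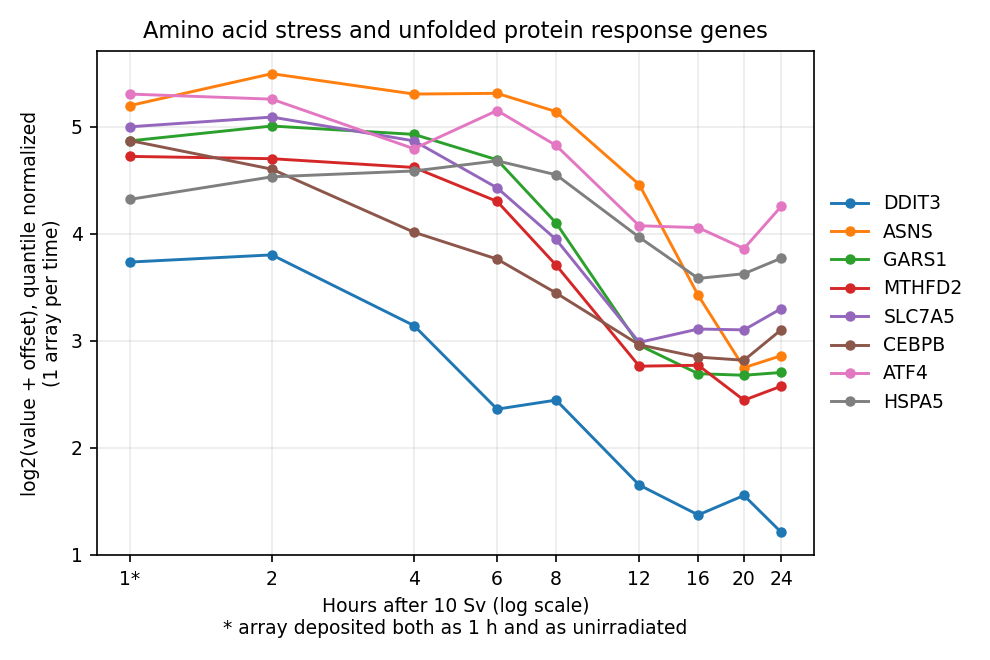
Normalized log2 level (vertical axis) of 8 unfolded protein response and amino acid stress genes against hours after 10 Sv (log scale), 1 array per point; the first point is the shared array. ASNS stayed between 5.14 and 5.50 until 8 h and was 2.75 at 20 h, while DDIT3 was already at 2.36 by 6 h.

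Of 23 tested G2/M and mitosis genes 5 fell, 0 rose and 18 did not pass (10 fell adjusted over the list alone). The examples were HMGB2, ZWINT, a kinetochore protein (-0.33, adjusted p = 0.00662), CKS1B (-0.32, 0.0225) and CKS2 (-0.22, 0.0461), both partners of cyclin-dependent kinases. The camera adjusted p was 2.26e-08, and adjusted p = 0.0603 with an estimated correlation and 0.00183 with fry. Of 36 tested G1/S and DNA replication genes 6 fell, 0 rose and 30 did not pass (adjusted over the list alone 13 fell and 1 rose). Their camera adjusted p was 3.51e-06, and adjusted p = 0.10 with an estimated correlation and 0.00259 with fry. The helicase gene MCM2 fell by 0.19 (adjusted p = 0.00398), the thymidine kinase gene TK1 by 0.32 (0.0284), the flap endonuclease gene FEN1 by 0.25 (0.0284) and UNG, which removes uracil from DNA, by 0.17 (0.0373). CCNB1 (slope -0.21, adjusted p = 0.0690), CDK1 (-0.16, 0.172), TOP2A (-0.07, 0.516) and CCNE1 (-0.01, 0.957) did not pass. Without 6 h CCNB1 did (0.0437). Other probe sets, lower in mean signal, fell more steeply for CCNB1 (-0.36) and TOP2A (-0.21 and -0.23). Those of CDK1 had slopes of 0.03 and -0.08, and that of CCNE1 -0.02. Leaving out 1 array in turn ended the call of UNG for 8 of 9 arrays (adjusted p from 0.0514 to 0.168), of CKS2 for 7 (0.0542 to 0.188), of FEN1 for 5 (0.0507 to 0.104), of TK1 for 4 (0.0567 to 0.0862) and of CKS1B for 3 (0.0682 to 0.0829).

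Of 15 tested replication-dependent histone genes 4 rose, 0 fell and 11 did not pass (8 rose adjusted over the list alone). H2BC21 rose by 0.23 (adjusted p = 0.0245), H2BC15 by 0.22 (0.0245; its other probe set, low in signal, had a slope of -0.05), H2BC6 by 0.21 (0.0273) and H2AC17 by 0.20 (0.0478). The camera adjusted p was 3.64e-05, and adjusted p = 0.0603 with an estimated correlation and 0.00197 with fry. H2BC21 was highest at 16 h, the array with the raised 3 prime to 5 prime ratios. The call of H2AC17 was lost without any 1 of the 9 arrays (adjusted p from 0.0562 to 0.156), that of H2BC6 without 1, 2, 20 or 24 h (0.0661 to 0.0837) and that of H2BC15 without 2, 20 or 24 h (0.0683 to 0.0895).

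Of 28 tested p53 target genes 4 rose with time, 0 fell and 24 did not pass (5 rose adjusted over the list alone). They were ACTA2, TP53I3, ASTN2 and BAX, a pore-forming death protein (0.17, adjusted p = 0.0328). The camera adjusted p was 9.15e-05, with an adjusted p = 0.344 with an estimated correlation and 0.861 without the 1 h array. With fry the p53 list did not pass either (adjusted p = 0.145). Of 17 tested senescence and lysosome genes only the growth factor binding protein gene IGFBP2 rose (0.14, adjusted p = 0.0245), 0 fell and 16 did not pass (3 rose adjusted over the list alone). That list had a camera adjusted p of 0.0279, an adjusted p = 0.10 with an estimated correlation, and 0.237 and 0.0632 without 1 h and without 24 h; it was also lost without a filter (0.151) and without the intensity trend (0.0540). The call of BAX was lost for 7 of 9 arrays left out (adjusted p from 0.0515 to 0.0888) and that of IGFBP2 without 2, 20 or 24 h (0.0689 to 0.111). The other BAX probe sets, all lower in mean signal, had slopes of 0.55, 0.22, 0.03 and 0.23.

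The number of genes past the trend's threshold depended on single arrays. Without 2 h, 12 rose and 33 fell; without 20 h, 15 rose and 41 fell; without 12, 4 or 8 h, 20, 27 or 27 rose; without 24 h, 48 fell. Without both 16 and 20 h, the arrays with the highest 3 prime to 5 prime ratios, 4 rose and 20 fell. Genes that rose made up 30.9% of the calls, against 14.9% with values as deposited and 16.7% without 16 and 20 h.

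The curved time course asked which genes followed time along a line or a curve, and a call does not show a return to the first level. CDKN1A, the p53-induced cyclin-dependent kinase inhibitor p21, went from a log2 level of 2.83 on the shared array to 5.65 at 4 h and 5.84 at 6 h, 8.07-fold higher, and was 4.91 at 24 h (adjusted p = 0.000678). DDB2, a damage recognition factor of nucleotide excision repair, was 4.92-fold higher at 6 h and 3.37-fold higher at 24 h (adjusted p = 0.00109). GLUL, glutamine synthetase, was 2.85-fold higher at 6 h (adjusted p = 0.000576), while the beta tubulin gene TUBB dipped to a ratio of 0.584 at 4 h and stood at 1.22 at 24 h (adjusted p = 0.000369). The actin-related ARPC1B and the ubiquitin ligase subunit gene RBCK1 were highest at 6 h and 2 h, and at 24 h had ratios of 0.580 and 0.630 (adjusted p = 0.00102 and 0.00131).

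Among 28 tested p53 target genes 11 were curved, 10 of them arched and 5 of these highest at 4 or 6 h (16 curved adjusted over the list alone). The expected number was 1.38 (Fisher's exact test, adjusted p = 3.51e-07). That p-value takes the genes as independent, while the inter-gene correlation of this list was estimated at 0.26 in the trend. PPM1D, a phosphatase that ends damage signalling, peaked at 4.42-fold at 4 h, GDF15, a secreted stress cytokine, at 2.49-fold at 4 h, XPC, another repair factor, at 2.62-fold at 6 h, the replication clamp gene PCNA at 3.23-fold at 8 h and TP53I3 at 7.81-fold at 12 h. MDM2, the ubiquitin ligase that degrades p53, had 2.50-fold at 6 h without passing (adjusted p = 0.0524), as had GADD45A with 3.26-fold at 4 h (0.165) and the death receptor gene TNFRSF10B with 2.08-fold at 6 h (0.134). MDM2 passed without 16 h (0.0496) and without the intensity trend (0.0351), and the other 2 without 8 h (0.0303 and 0.0444). The call was lost without 6 h for PPM1D (0.0567), without 1 or 6 h for GDF15 (0.140 and 0.0524) and without 4, 6 or 8 h for XPC (0.0539 to 0.0648). The death receptor gene FAS was below the filter and had 4.55-fold at 6 h, untested. ATF3, also below the filter, went from a log2 level of 0.62 to -1.12 at 24 h.

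**Figure D2:**
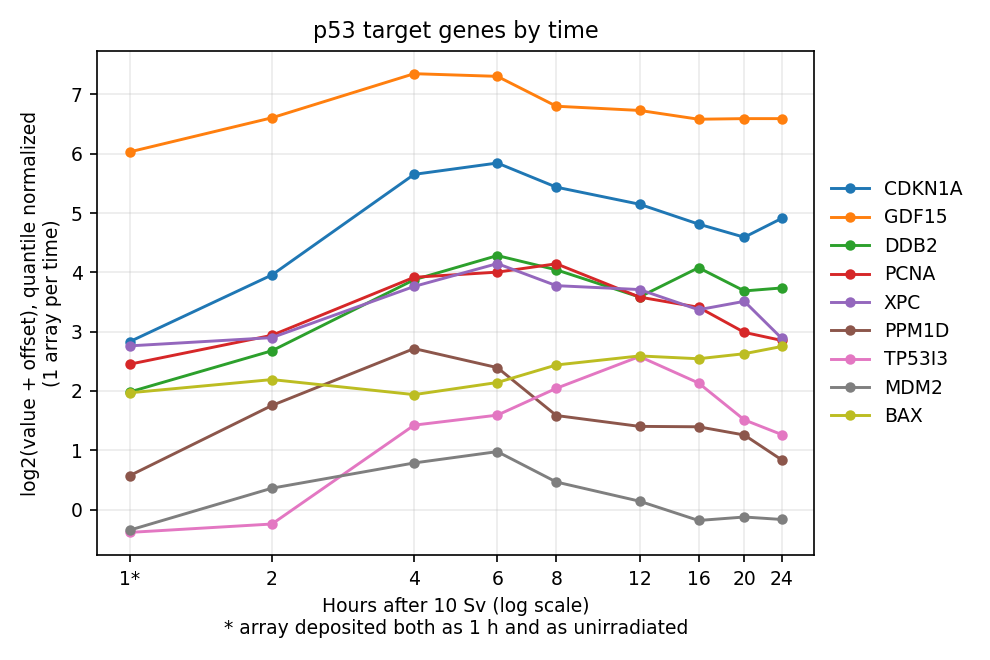
Normalized log2 level (vertical axis) of 9 p53 target genes against hours after 10 Sv (log scale), 1 array per point; the first point is the shared array. CDKN1A was highest at 6 h with 5.84 and GDF15 at 4 h with 7.35, while BAX was highest at 24 h with 2.75.

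Of the 28 stress and amino acid genes 22 were curved (22 adjusted over the list alone; expected 1.38, Fisher's exact test adjusted p = 4.25e-23). The test includes the slope and 18 of the 28 had fallen in the trend, so these calls are no separate sign of a curve. Fisher's exact test also ignores the inter-gene correlation of this list, estimated at 0.40 in the trend. GARS1, for example, fell without a return, with log2 levels of 4.87 on the shared array, 4.69 at 6 h and 2.96 at 12 h. Of 23 G2/M genes 8 were curved (10 adjusted over the list alone; adjusted p = 5.45e-05). Among 25 androgen-responsive genes 4 were curved (9 adjusted over the list alone; adjusted p = 0.0998): KLK2, a prostate kallikrein, dipped to a ratio of 0.538 at 6 h (adjusted p = 0.0154), TMPRSS2, a serine protease, to 0.489 at 6 h (0.0165), FASN, fatty acid synthase, was highest at 24 h (0.0154) and FKBP5, a chaperone of steroid receptors, was highest at 2 h (0.0329). KLK3, the gene of prostate-specific antigen, did not pass (0.677 at 12 h, adjusted p = 0.106), nor did MYC (0.115, but 0.0152 without 16 h and 0.0325 without 16 and 20 h) or BCL2L1 (0.721). The call was lost without 6 h for KLK2 (0.0615), without 4, 6 or 24 h for TMPRSS2 (0.0580 to 0.0643), without 2, 4, 20 or 24 h for FASN (0.0526 to 0.0786) and without 2, 4, 6, 8 or 20 h for FKBP5 (0.0528 to 0.128). As deposited, KLK2 and FASN had an adjusted p of 0.172 and 0.236.

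In total 244 genes were curved, 173 arched and 71 dipped, and 115 of them were also in the trend. Without 20, 4, 6 or 2 h the count was 140, 144, 144 or 152, and without 16 and 20 h it was 163. With a quadratic in hours in place of log2 hours the calls of CDKN1A (adjusted p = 0.246), DDB2 (0.0897), TUBB (0.0554), PPM1D (0.364), GDF15 (0.551), XPC (0.0815), PCNA (0.0915), KLK2 (0.263) and TMPRSS2 (0.0993) were lost.

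The early window asked what had changed by 2 and 4 h. The p53 target genes were higher as a list: the median difference from the shared array was 0.59, with 24 of 28 genes higher (camera adjusted p = 1.09e-14, and adjusted p = 0.315 with an estimated correlation). The median was 0.3185 without 4 h, 1.006 without 2 h and 0.386 with the array under both labels. With fry the p53 list had an adjusted p of 0.366, and 0 lists passed early. No member passed over all genes, and 7 were higher adjusted over the list alone. CDKN1A had a difference of 1.97 (SE 0.50, limma adjusted p = 0.952), PPM1D 1.66 (SE 0.45) and GADD45A 1.41 (SE 0.36). Without 2 h or without 4 h the early window held 1 array against 1, and its error came from the other windows alone. Respiratory chain genes had a median of 0.08 with 38 of 50 higher and 0 passing, also adjusted over the list alone (camera adjusted p = 0.00597, and adjusted p = 0.522 with an estimated correlation); without 4 h this list did not pass (median 0.03, 0.669), nor without the intensity trend (0.0514), and its median was 0.143 without 2 h and 0.165 as deposited.

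A single gene passed early, the transcription factor gene ERG, lower by -2.06 (SE 0.27, n = 2 against 1 array, limma adjusted p = 0.0494). Its log2 level was 1.93 on the shared array, 0.00 at 2 h, -0.26 at 4 h and 1.66 at 6 h. Unadjusted, 147 genes had p under 0.05, against 247 from chance. The 3 other ERG probe sets, all with a lower mean signal, did not follow it (correlations across arrays of -0.261, 0.032 and -0.250). The ERG call was lost without 2, 4, 6, 8, 12 or 20 h (adjusted p = 0.0619, 0.375, 0.111, 0.163, 0.151 and 0.120), the count was then 0 except without 2 h, where it was 2, and ERG passed in 6 of 18 other settings.

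The middle window asked what had changed by 6 to 12 h. No gene passed in limma, though 345 had an unadjusted p under 0.05. The smallest p belonged to TYMS, thymidylate synthase (1.43, SE 0.21), DDIT4, an inhibitor of growth signalling (-1.19, SE 0.20), RAB1A, a vesicle transport gene (0.56, SE 0.09) and PLXNB2 (1.25, SE 0.22), each with an adjusted p of 0.1035 and n = 3 against 1 array. CDKN1A had 2.64 (SE 0.47). Without 2 h and without 4 h 9 genes passed, among them TYMS, DDIT4, PLXNB2 and CDKN1A, and without 6 h 1.

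As lists, 9 passed in the middle window. With fry only the interferon-stimulated and the senescence and lysosome lists did (both adjusted p = 0.0426). The p53 target genes had 0.0555 with fry. The p53 target genes had a median of 0.81 with 26 of 28 higher (12 higher adjusted over the list alone; camera adjusted p = 8.37e-18, adjusted p = 0.215 with an estimated correlation). The stress and amino acid genes had a median of -0.46 (6 lower adjusted over the list alone; 4.45e-07, adjusted p = 0.287 with an estimated correlation), and the G2/M genes -0.25 (3 lower; 6.01e-04, adjusted p = 0.284 with an estimated correlation). Respiratory chain genes (median 0.11; camera adjusted p = 0.00138, estimated 0.295), senescence and lysosome genes (0.17; 0.00943, estimated 0.220), proteasome genes (0.12; 0.0304, estimated 0.486), interferon-stimulated genes (0.10; 0.0325, estimated 0.258) and histone genes (0.25; 0.0363, estimated 0.295) were higher as lists. G1/S genes were lower as a list (-0.18; 0.0359, estimated 0.338). Adjusted over the list alone, 2 respiratory chain genes and 1 senescence and lysosome gene were higher, 0 interferon-stimulated and 0 histone genes passed. The members that passed went against their list for proteasome (0 higher, 1 lower) and G1/S genes (2 higher, 0 lower). The stress and amino acid median was -0.285 without 12 h, the respiratory chain median 0.0534 without 6 h and 0.178 as deposited, the interferon median 0.165 without 6 h and the senescence median 0.106 without 8 h. The call was lost without 12 h for G1/S (0.111), histone (0.140) and interferon-stimulated genes (0.0535), without 8 h for proteasome genes (0.206), and without 2, 4 or 8 h for G1/S genes (0.0941, 0.0745 and 0.0641). It was also lost without a filter for histone (median 0.0375, 0.322), interferon-stimulated (0.280) and senescence genes (0.0507), above the 60th percentile for histone (0.0574), interferon-stimulated (0.127) and G1/S genes (0.234), without the intensity trend for histone and proteasome genes (both 0.0576) and as deposited for proteasome genes (0.0662).

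The late window, which includes the hour at which the control was collected, asked what differed at 16 to 24 h. The lowest differences from the shared array among called genes were those of DDIT3, lower by -2.36 (SE 0.32), ASNS by -2.19 (SE 0.31), CEBPB by -1.95 (SE 0.29), PCK2 by -1.90 (SE 0.29), STC2 by -1.81 (SE 0.29), the carrier gene SLC25A36 by -1.52 (SE 0.25), DDIT4 by -1.49 (SE 0.20) and the arginine transporter gene SLC7A1 by -1.46 (SE 0.21), with n = 3 arrays against 1 and limma adjusted p from 0.0298 to 0.0369. ACTA2 was the only gene called higher, by 3.02 (SE 0.52, adjusted p = 0.0496). In all 13 genes were lower and 1 higher, with 532 at an unadjusted p under 0.05.

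Of the 28 stress and amino acid genes 5 were lower and 23 did not pass (23 lower adjusted over the list alone; median -1.11, camera adjusted p = 9.98e-24, adjusted p = 0.177 with an estimated correlation). The p53 target genes still had a median of 0.50, with ACTA2 passing and 27 not (7 higher adjusted over the list alone; 2.92e-09, adjusted p = 0.193 with an estimated correlation). G2/M genes had a median of -0.42 (0 passing; 5 lower adjusted over the list alone; 8.10e-07, estimated adjusted p = 0.177), G1/S genes -0.25 (0 passing; 1 lower and 1 higher adjusted over the list alone; 0.000665, estimated 0.229), histone genes 0.36 (0 passing; 1 higher adjusted over the list alone; 0.000665, estimated 0.195) and senescence and lysosome genes 0.18 (0 passing; 1 higher adjusted over the list alone; 0.0109, estimated 0.177). The senescence list did not pass without 24 h (0.0560), without a filter (0.177) or with the array under both labels (0.0502). With fry the stress and amino acid, G2/M and senescence lists passed late (each adjusted p = 0.0460). The p53 target genes (0.0780) and the G1/S and histone genes (both 0.0774) did not.

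The late count was 0 without 8, 20 or 24 h, 33 without 6 h and 48 without 12 h. It was also 0 without 16 and 20 h. The calls of all 9 genes named above were lost without 8, 20 or 24 h, with adjusted p from 0.0524 to 0.0922, and those of ACTA2, CEBPB, SLC25A36 and STC2 also without 16 h (0.0724, 0.0526, 0.0591 and 0.0636).

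Late against early compared 16 to 24 h with 1 to 4 h, 3 arrays each. ASNS was lower by -2.32 (SE 0.21), GARS1 by -2.24 (SE 0.31), DDIT3 by -2.18 (SE 0.22), MTHFD2 by -2.08 (SE 0.28), PCK2 by -1.88 (SE 0.20), SLC7A5 by -1.81 (SE 0.26) and CEBPB by -1.57 (SE 0.22), with limma adjusted p from 0.000681 to 0.00316. A probe set for the immunoglobulin heavy chain locus IGH was lower by -1.90 (SE 0.27), but the other IGH probe set did not follow it (correlation -0.057, trend slope 0.09 against -0.46). ACTA2 (2.25, SE 0.42), APOD (1.73, SE 0.25), CEL (1.60, SE 0.31), APLP1 (1.07, SE 0.17) and LRPAP1 (1.06, SE 0.13) were higher, as were TOP3A (1.74), ANKRD12 (1.23; its other probe set had a correlation of 0.394) and SNAPC4 (1.19). In all 149 genes were lower and 73 higher. The call was lost without 2 h for ACTA2 (adjusted p = 0.0578) and CEL (0.0682), without 1 or 2 h for TOP3A (0.0885 and 0.123), and with its first probe set kept without 16 or 20 h (0.0739 and 0.0696), without 1, 2, 4, 16 or 24 h for ANKRD12 (0.0879 to 0.158) and without 1, 4, 16, 20 or 24 h for SNAPC4 (0.0511 to 0.0864).

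Of 28 stress and amino acid genes 22 were lower and 6 did not pass (23 lower adjusted over the list alone; median -0.93, camera adjusted p = 3.07e-25, adjusted p = 0.113 with an estimated correlation). HSPA5 was among them (-0.82, adjusted p = 0.0127). Of 23 G2/M genes 7 were lower, among them ZWINT (-1.26), UBE2S, a ubiquitin-conjugating enzyme (-0.67), PLK1 (-1.42) and CCNB1, cyclin B1 (-0.68), and 16 did not pass (12 lower adjusted over the list alone; 6.01e-08, adjusted p = 0.113 with an estimated correlation). Of 36 G1/S genes 6 were lower, such as TK1 (-1.17) and MCM4 (-1.01), and 30 did not pass (10 lower adjusted over the list alone; 1.66e-05, adjusted p = 0.149 with an estimated correlation). Of 15 histone genes H2BC21 (0.93) and H4C9 (0.69) were higher and 13 did not pass (6 higher adjusted over the list alone; 0.000158, adjusted p = 0.149 with an estimated correlation). Both were highest at 16 h, the array with the raised 3 prime to 5 prime ratios. With fry the stress and amino acid, G2/M, G1/S and histone lists passed (adjusted p from 0.00420 to 0.00759). Of 44 ribosomal protein genes 4 were higher, such as RPS15 (0.58) and RPS21 (0.55), RPS16 was lower (-0.22) and 39 did not pass (6 higher and 2 lower adjusted over the list alone; 0.0317, adjusted p = 0.368 with an estimated correlation); the list did not pass without 2 h or 20 h (0.0862 and 0.0994), without both 16 and 20 h (0.208), above the 60th percentile (0.05004) or without the intensity trend (0.163). Its median of 0.04 was 0.204 as deposited, 0.261 with 75th percentile scaling and 0.278 with equal trimmed means restored. The lower value of RPS16 depended on the scaling: its difference was 0.06 as deposited, 0.12 with 75th percentile scaling and 0.13 with equal trimmed means restored, without a call. Leaving out 1 array in turn ended the call of CCNB1 for all 9 arrays (adjusted p from 0.0581 to 0.174), of TK1 for 5 (0.0578 to 0.0786), of PLK1 (0.0618 to 0.123), UBE2S (0.0505 to 0.0935) and H4C9 (0.0591 to 0.115) for 4 and of HSPA5 (0.0527 and 0.0659), MCM4 (0.0634 and 0.1004) and RPS16 (0.0502 and 0.0556) for 2.

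Without 2 h 20 genes were higher and 54 lower; without 20 h 35 and 97; without 4 h 47 and 80; without the shared array 93 were lower. Without 16 and 20 h 12 were higher and 87 lower. Genes that were higher made up 32.9% of the calls, 12.4% with values as deposited and 12.1% without 16 and 20 h.

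Single times against the shared array had no test. The p53 target genes had medians of 0.37, 0.99, 1.03, 0.64, 0.63, 0.55, 0.56 and 0.44 from 2 to 24 h. These lay above the medians of all or nearly all of 10000 random lists at each time. The random lists make no allowance for inter-gene correlation, estimated at 0.26 for the p53 list in the trend. Every difference uses the same shared array, so a low reading there would raise all times at once. Stress and amino acid genes had 0.08 at 2 h, -0.34 at 8 h, -0.86 at 12 h and -1.05 at 24 h. At 2 h the highest differences among tested genes were those of DXO (1.86), RAPGEF3 (1.76), MIR9-1HG (1.67), C15orf39 (1.63) and ACKR2 (1.61), and the lowest those of SIX3 (-1.96), ERG (-1.93), GPR143 (-1.77), CYP19A1 (-1.68) and PRCP (-1.56). The other probe sets of CYP19A1 (correlations across arrays of -0.857, -0.189, -0.214 and 0.108), MIR9-1HG (0.279 and -0.069) and RAPGEF3 (0.375) did not follow the chosen ones or did so weakly. At 2 h 45 genes were more than 2-fold higher than on the shared array and 37 lower, against 75 and 128 at 24 h.

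**Figure D3:**
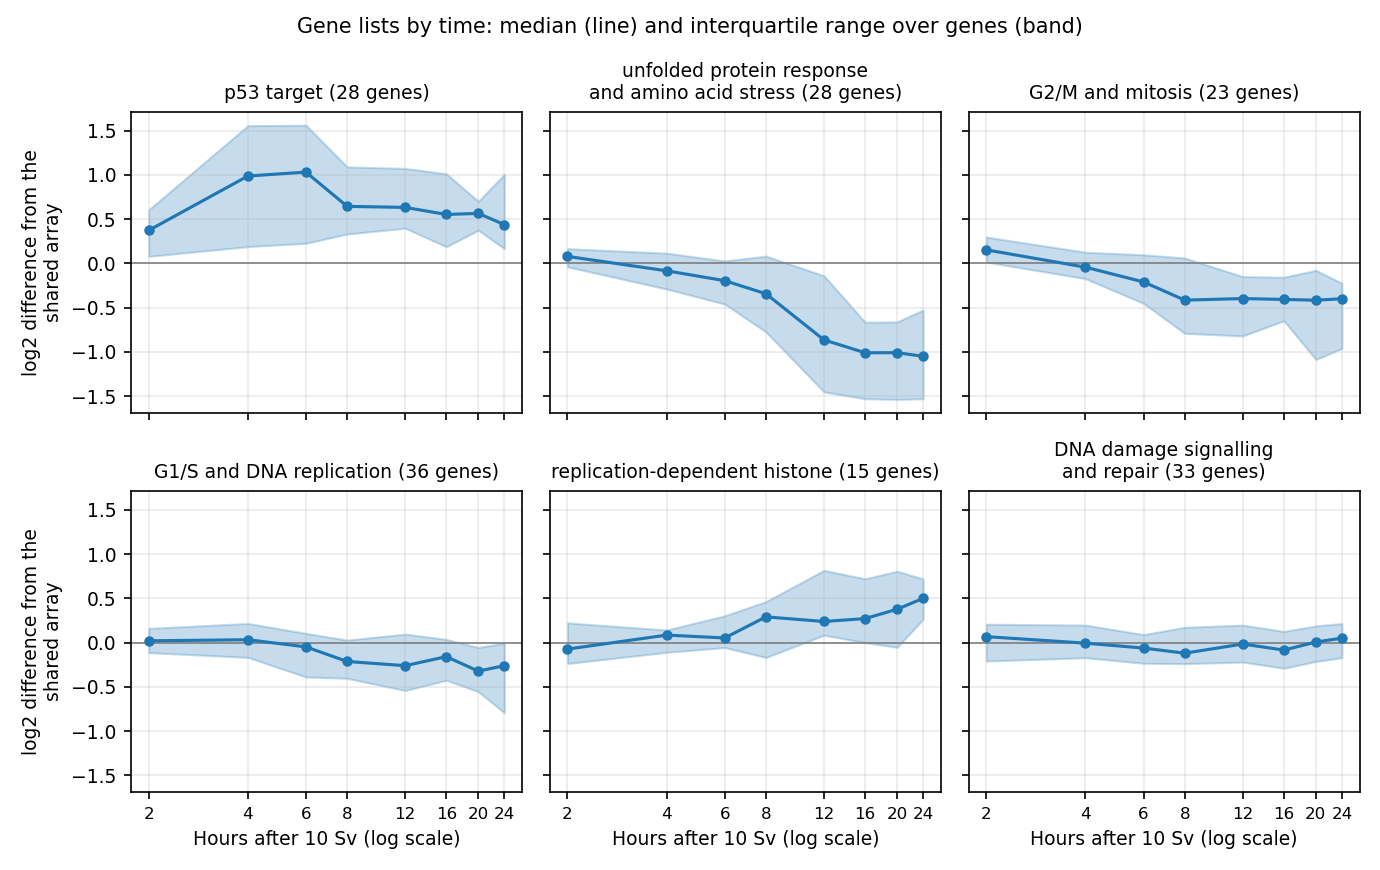
Median log2 difference from the shared array (line) and interquartile range over genes (band) for 6 gene lists against hours after 10 Sv (log scale), 1 array per time. The p53 target list peaked at 1.03 at 6 h, the stress and amino acid list reached -1.05 at 24 h, and DNA damage signalling and repair genes stayed between -0.12 and 0.07.

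The other 14 lists did not pass in the time trend in the main setting. The camera adjusted p was 0.636 for DNA damage signalling and repair, 0.0701 for apoptosis, 0.177 for immediate early, 0.424 for NF-kB, 0.532 for interferon-stimulated, 0.620 for androgen-responsive, 0.609 for cholesterol and lipid synthesis, 0.532 for heat shock, 0.620 for NRF2 and oxidative stress, 0.0701 for ribosomal protein, 0.532 for respiratory chain, 0.421 for proteasome, 0.677 for glycolysis and hypoxia and 0.916 for neuroendocrine genes. The result for ribosomal protein genes depended on the scaling. Their median slope of 0.006 was 0.0557 as deposited, 0.0694 with 75th percentile scaling and 0.0737 with equal trimmed means restored, each with a call (adjusted p from 3.34e-19 to 1.65e-12). The list also passed without 1, 4 or 6 h (0.00180, 0.0343 and 0.0384). Late against the shared array this list had an adjusted p of 0.268 in the main setting and passed with the same 3 scalings (1.26e-12 to 2.70e-07). Early it had 0.142 and a lower median that passed with the last 2 (0.0165 and 0.00414). Apoptosis genes passed in the trend with fry (0.00277) and without 16 and 20 h (0.0411). Immediate early genes passed with fry (0.0356). For interferon-stimulated genes the median slope (0.02) and the mean (-0.0014) differed in sign, as they did for androgen-responsive genes (0.0045 and -0.02).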

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

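The tests of the 16 h array were chosen only after its values had been seen. The 16 h array stood out in measurements that the comparisons did not use, the control probe sets, where it held the highest value of all arrays. The 3 prime probe set of 18S ribosomal RNA read 1.533 at 16 h against 0.179 on the shared array, its middle probe set 0.267 against 0.0581 and its 5 prime probe set 1.027 against 0.0888. The 3 prime 18S probe set also read 0.938 at 20 h, against 0.227 at 12 h, while the 5 prime one read 0.110 and 0.0387. All 18S readings on the shared array, and the middle one at 16 h, lay below the offset of 0.292. The Alu repeat probe set read 279.5 against 195.5, but its neighbours in time were closer, with 251.7 at 12 h and 256.5 at 20 h. The 3 prime to 5 prime ratio was 3.299 against 1.535 for ACTB and 2.378 against 1.148 for GAPDH.

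Shortened or degraded RNA in the 16 h array is a candidate explanation. Of 4 transcripts with probe sets at both ends, 3 had their highest ratio of all arrays at 16 h; the exception was TFRC, with 0.896 at 16 h, against its range of 1.24 to 3.17 on the other arrays. A transcriptional change peculiar to 16 h was not tested, since there was only 1 array at 16 h. Between them no value decides, and genes that were highest at 16 h, such as ACTA2, TOP3A, H2BC21 and SDHA, share this doubt.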

How the results depend on the processing

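A few settings were chosen only after the data had been seen: signals restored to equal trimmed means, the shared array under both labels, the fit without 16 and 20 h, and late against early without the shared array. For named genes, 874 comparisons without 1 array kept the side of the threshold, 266 lost the call, 15 gained it and 2 reversed; under the other settings 1062 kept it, 259 lost it, 3 gained it and 4 reversed. The reversed were CCNE1 in the trend (-0.0101; 0.0146 without 16 and 20 h, -0.0264 to 0.0244 without 1 array, above 0 without 1 or 20 h) and RPS16 late against early (-0.219; 0.0587 as deposited, 0.115 with 75th percentile scaling, 0.132 with equal trimmed means restored). Where a setting changed the probe set with the highest mean, the new one was used; among named genes this was only TOP3A, whose first probe set was also followed, a choice made after the data had been seen. Single genes were not followed with all probe sets, nor where the 60th percentile filter removed them. For lists, 221 comparisons without 1 array kept the side of the threshold, 14 lost a call and 11 gained it; under the other settings 267 kept it, 58 lost it, 17 gained it and 3 reversed. Genes below the 40th percentile of signal were filtered out and not tested, and 1 array per time leaves the control of every window a single array. No paired analysis was possible because each time had 1 array and the labels pair none of them. With values as deposited 11 genes rose in the trend (42 in the main setting), 6 passed late against the shared array (14) and 17 were higher late against early (73). With 75th percentile scaling 27 rose. Without a filter 24 rose and 57 fell (94), and the early and late counts were 0 (1 and 14). Above the 60th percentile 43 passed late. Without the intensity trend 19 rose and 56 fell, 131 were curved (244), early and late counts were 0, late against early gave 30 higher and 79 lower (149), and 1 list passed early (2). With all probe sets 3 passed early and 9 late. Over hours 69 rose and 171 fell; with the control at 0 h 19 rose and 47 fell; the fitted 24 h value gave 85 late calls. The early count was 0 with the offset doubled, with equal trimmed means restored and with the array under both labels. Without 16 and 20 h 4 rose, 20 fell, early and late counts were 0, and late against early gave 12 higher and 87 lower. With an estimated correlation 0 lists passed in any of the 5 comparisons; with fry 0 passed early, 2 in the middle (9), 3 late (6) and 8 late against early (5). The ribosomal protein list reversed in the middle window: its median was -0.03 in the main setting without a call, and 0.0935 as deposited, 0.0590 with 75th percentile scaling and 0.0565 with equal trimmed means restored, each with a call. Leaving out 1 array at a time gave 12 to 51 rising and 33 to 106 falling genes, 140 to 273 curved genes, 0 to 2 early, 0 to 9 middle and 0 to 48 late calls, 20 to 80 higher and 54 to 160 lower genes late against early, and 5 to 7 trend, 1 to 2 early, 6 to 10 middle, 5 to 6 late and 4 to 7 late against early lists. Fewer arrays lower the residual degrees of freedom; for the other settings the cause was not tested.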

Other observations

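The tests of time in culture and of the scaling behind the histone genes, and the bound used for shared histone probe sets, were chosen only after the result was seen. Some genes moved in lists that did not pass. In the time trend the thioredoxin gene TXN (0.15, adjusted p = 0.0116) and the peroxiredoxin gene PRDX1 (0.10, 0.0221) rose, 2 of 28 tested oxidative stress genes. Of 50 respiratory chain genes SDHA (0.20, 0.0150), UQCRB (0.14, 0.0245) and ATP5PD (0.14, 0.0413) rose, and of 44 ribosomal protein genes RPS15 (0.15, 0.0183), RPS21 (0.14, 0.0183) and RPL10A (0.08, 0.0397) rose. The sterol reductase gene TM7SF2 (0.15, 0.00399), the interferon-stimulated gene BST2 (0.14, 0.0484) and GAPDH (0.11, 0.0417; slope -0.12 for its other probe set, low in signal) rose. Leaving out 1 array in turn ended none of the calls of TXN and TM7SF2, and for the others ended between 1 (RPS21) and 8 (ATP5PD and BST2) of 9; as deposited all but RPS21 and GAPDH were lost (adjusted p from 0.0649 to 0.290).

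Of 33 tested DNA damage signalling and repair genes only H2AX, the histone variant phosphorylated at breaks, fell (-0.17, adjusted p = 0.0248), and BARD1, the partner of BRCA1, dipped to a ratio of 0.588 at 4 h (curved adjusted p = 0.0132). The mitochondrial chaperone genes HSPA9 (-0.29, 0.0141) and HSPD1 (-0.14, 0.0177) fell, as did FKBP5 (-0.27, 0.0341) and DDIT4 (-0.31, 0.000894). The calls of H2AX, HSPA9, HSPD1 and FKBP5 were lost for 3, 2, 3 and 6 of the arrays left out in turn, and as deposited those of BARD1 (adjusted p = 0.149) and HSPD1 (0.206) were lost. Thymidylate synthase, TYMS, arched to 2.82-fold at 12 h (0.0102, and 0.0636 without 1 h). At 8 h 8 of 9 luminal prostate markers were below the shared array, with a median of -0.46. The median was -0.09 at 2 h, -0.16 at 4 h, -0.21 at 6 h, -0.29 at 12 h, -0.19 at 16 h, -0.05 at 20 h and -0.02 at 24 h. None fell in the trend (1 fell adjusted over the list alone). In the middle window 9 of 9 had lower values and 0 passed (2 lower adjusted over the list alone). Late against early 1 was called lower, while 7 of 9 had a positive difference.

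Chance as a source of the counts was tested by giving the 9 arrays other orders in time. In 100 orders only 1, the real one, gave as many trend genes (136, the next 124) and as many curved genes (244, the next 87). A random order is thus an unlikely source of either count, though 1 came near for the trend. The orders show only that order in time matters, not what changed with time. For the trend lists 10 of 100 orders gave as many as the real 6, up to 8, so chance cannot be excluded for the number of lists at the preset correlation. The 6 arrays of late against early allow 10 splits, too few to give a share under the threshold: 1 gave as many genes (222, the next 1) and 4 gave as many lists (5, up to 8).

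Of 28 stress and amino acid genes 18 fell with time, with a median slope of -0.29 (adjusted p = 0.0603 with an estimated correlation). RNA quality of the 16 h and 20 h arrays as the whole cause is argued against by the slope without them, -0.2421 (interquartile range -0.37 to -0.11), and the shared array by the slope without it, -0.3156, with 28 of 28 genes falling in value. Time in culture rather than irradiation stays open. The unirradiated and 1 h columns differ in 0 probe sets, so the shared array may be either sample. As the control, collected with the 24 h cells, it would match the 24 h array in time in culture. As the 1 h array, it would leave no unirradiated cells to compare with. A response to irradiation was therefore not separated from medium use over the day.

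Of 15 replication-dependent histone genes 4 rose and 11 did not pass, with a median slope of 0.14 (adjusted p = 0.0603 with an estimated correlation; median 0.0750 without a filter and 0.0862 without 2 h). RNA quality of the 16 h and 20 h arrays as the whole cause is argued against by a median of 0.1002 without them (12 of 15 genes positive). That median was below the 0.14 of all arrays, so a part in the rise stays open. Under the 4 scalings the histone median ran from 0.1275 as deposited (interquartile range 0.045 to 0.164) to 0.1439. The median slope of all genes ran only from -0.0111 to 0.0053 under them, small beside 0.14. The 4 scalings were thus too alike for these medians to decide on scaling as a cause. A scaling error common to all 4 was not tested. Probe sets shared between near-identical histone genes cannot be told apart from a change in many genes, since 7 of the 15 tested probe sets are of a shared type: 6 of these 7 and 6 of the 8 others had a positive slope, 2 of each were called, and the medians were 0.158 and 0.0784 (interquartile ranges 0.101 to 0.186 and 0.0480 to 0.154). The bound written beforehand was a minority of the probe sets, which 7 meets by less than 1 probe set; as the type records only how the probes were designed, that margin was judged, after the value was seen, to decide nothing. A response to irradiation stays open and was not separated from time in culture.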
